A study of Mus musculus with 115 samples.

How the data were processed

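Genomic DNA from pancreatic cancer cell cultures of mice was compared with DNA from tail tissue on 2-colour oligonucleotide arrays (array comparative genomic hybridization), in which each probe measures how much of its sequence the culture holds relative to the tail. Per the labels, culture and tail of an array came from the same mouse, the mice had a mixed C57Bl/6 and 129S6/SvEv background, and cultures were used at under 10 passages. The 115 arrays were of 2 formats: 71 larger ones (244k) held the PK and PKPB cultures. The other 44, smaller ones (60k), held the PKC, PKP and PKT cultures. Format and genotype are therefore confounded across the formats, and no test was made between them.

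The scanner files give, per the file headers, Feature Extraction 10.7.3.1 for the 71 larger arrays and 11.0.1.1 for the 44 smaller ones. Per the file headers, the processed intensity of each channel was background-subtracted, spatially detrended and dye-normalized linearly within the array, with intensity-dependent (lowess) normalization off on all 115 arrays, and the deposited log10 ratio is that of red (Cy5) over green (Cy3) processed intensity. The authors' value tables, in log2 units, were compared with each array's scanner values: the slope was 0.999 to 1.00 and the correlation 0.997 to 1.00 on every array, with a constant offset per array of −0.14 to 0.18. The scale of these deposited log2 values is thus known, and they run in the direction that the channel fields give, while how the offset was chosen is not given in the sources used here. The medians of the authors' columns ran from −0.09 to 0.25. The files give positions on mm9, and 1 array names mm8 in its header; its probes were placed by name.

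The direction of each ratio was taken from the channel fields of the labels (culture in Cy5 on the 244k arrays and in Cy3 on the 60k arrays). The labelling protocol text names Cy3 for the sample on all arrays, which contradicts the fields for the 244k format, so anchors of known direction were set before the data were examined, together with the groups, the tests, the gene lists and most of the other processing settings tried. No pair of arrays of a format correlated below −0.21 over all autosomal probes.

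Ratios of processed intensity were turned to culture over tail and taken to log2. Control spots and spots flagged as outliers in either channel were left out (0.0584% to 0.494% of spots on the 244k arrays and 0.137% to 0.792% on the 60k arrays). Saturated spots were kept, spots of one probe were averaged, and each array was centred on the median of its autosomal probes. A shift common to the whole genome, such as a change of ploidy, is not visible after centring. Of 235402 probes on the 244k array, 234018 had a chromosome position, as did all 55712 of the 60k array. Median processed intensity was 1004 to 1175 in the culture channel of the 244k arrays and 761 to 910 in that of the 60k arrays, and at least 98.1% of spots were well above background in either channel of every array. Noise, from differences between neighbouring probes, was 0.08 to 0.32 (log2) on the 244k arrays and 0.12 to 0.47 on the 60k arrays. For arrays, the number of arrays and probes limits the precision.

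Each chromosome was split into segments of equal copy number by least-squares change points (PELT, penalty of 3 times the noise variance times the natural logarithm of the number of probes, at least 3 probes), and neighbouring segments differing by under 0.1 were merged. Segments at 0.2 or above were called gains, at −0.2 or below losses, at 1 or above high-level amplifications and at −1.5 or below deep deletions. A gene took the value of the segment over the span of its probes, and where several segments met there, that of the one farthest from 0. Genes of 8 lists (89 genes) were placed by exact, unique matches of 60k probe sequences to GRCm38 with GENCODE vM21 (55606 of 55712 probes matched once), and the mm9 positions of the same probes are printed. No coordinate was converted between builds. The 244k array held no probe inside Cdkn2b, whose values there come from the segment that spans it. A genome of the build of the files was not used here, so the planned correction for GC content was replaced, after the data were seen, by one that used the probe matches on GRCm38 (windows of 1 kb and 100 kb).

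The mean log2 ratio of autosomal bins of 1 Mb with at least 3 probes (2403 bins on the 244k and 2391 on the 60k array) was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. PKPB and PK entered a fit of their own, and the 4 groups of the 60k arrays shared a fit and its estimate of spread, with PKT as the mean of its HET and HOM cultures weighted by their numbers. For metastases, the values of one mouse were averaged and the difference to its primary was tested against 0 over 7 mice, which the titles pair. Bins of a chromosome are not independent, so runs of called bins are given as regions. Single values were compared by two-sided permutation tests of the difference of means (100000 resamples, exact for HOM against HET and for the altered share over mice). The exact permutation of mouse labels, for correlations with the own and with other primaries, was one-sided. Shares were compared by Fisher's exact test and carry exact Clopper-Pearson 95% intervals. Whole-chromosome events (at least 80% of the covered length called) were set against 10000 permutations of chromosomes within each culture, focal events against the highest count in 1000 circular shifts of each culture along the genome, and gene lists against 10000 circular shifts. For the lists, each member was read at the 1 Mb bin that holds it, so that neighbouring genes of one bin share a value, and a score from the segments over each member's own probes was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and statmod 1.5.0 were also used.

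The text names 11 genes in every genotype (Kras, Cdkn2a, Cdkn2b, Mtap, Trp53, Tgfbr2, Smad4, Myc, Yap1, Nfkb2 and Gata6), other list members with a high-level amplification or deep deletion in at least 2 primary cultures of a genotype, the members of each list with the highest share of gains and of losses, up to 5 called regions per direction of each limma comparison by mean difference, and up to 5 peaks of the focal test per genotype and direction, with the annotated genes where 3 or fewer.

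Slide and scan day were read from the files. The 244k arrays had 1 array per slide and no scan day with both PK and PKPB primaries. On the 60k arrays, 6 PKC cultures shared a scan day with all PKP cultures, the other 10 PKC cultures had a day of their own, and all PKT cultures had another. PKT HET and PKT HOM shared 3 slides. No pair of arrays held identical values, and the highest correlation within a group was 0.84 (244k) and 0.75 (60k), so every array counted as a sample.

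The methods were tested on simulated data. With 50 probes at 0.3, 10 probes at 0.6 and 3 probes at −2, segmentation of 234018 simulated 244k positions found 100%, 100% and 100% of planted changes, and of 55712 simulated 60k positions 100%, 98% and 100%, but of 3 probes at 0.6 it found 16% and 0%. At a planted difference of 0.2, limma found 86% of changed bins for PKPB against PK and 31% for PKT HOM against PKT HET, where 15 unchanged bins were also called. In 20 simulated sets per genotype, focal deletions planted at Cdkn2a were found in 100%. A planted whole-chromosome loss was found in 100% in PK, 55% in PKPB, 60% in PKC, 65% in PKP and 30% in PKT. The gene-list test found a planted loss of the Cdkn2a neighbours in only 35% (PKPB) to 50% (PK and PKP) of them, and over the 20 sets it also called 5 unchanged lists in PK and 6 in PKP.

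Alternatives were normexp background correction of the spots' raw signals with an offset of 50, the authors' value tables, centring on the highest peak of segment means, leaving out probes dim in the tail, the call thresholds and segment rules, bins of 5 Mb, segment means, batch terms and leaving out replicates or mice. The GC correction, the authors' own centring, the probes shared by the formats and leaving out 3 arrays with discordant sex chromosomes were added after the data were seen. The normexp alternative, planned on mean signals, used median signals on the 244k arrays. Data of chromosomes X and Y entered no comparison.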

Results

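DNA copy number was measured in 115 cultures from mouse pancreatic cancers that carried activated Kras in the pancreas. Per the labels, each was set against tail DNA of the same mouse, which the sex chromosomes of 3 arrays put in question. The primary cultures came from 38 PK mice (activated Kras alone), 17 PKPB mice (activated Kras with PB, which the labels name without describing), 16 PKC mice (homozygous Cdkn2a deletion in the pancreas), 16 PKP mice (homozygous Trp53 deletion) and 12 PKT mice (Tgfbr2 deletion, heterozygous in 7, PKT HET, and homozygous in 5, PKT HOM). A further 16 cultures from PK mice came from metastases (12 liver, 3 lung, 1 lymph node). Values are log2 ratios of culture over tail, with the sign from the channel fields, which the labelling text contradicts for the PK and PKPB arrays. Positions are mm9, and errors are SD over cultures unless another is named. The series title names the dosage of Kras and evolutionary routes as the subject.

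The engineered genes were read first, since they check the labels and the sign. For each gene the probe with the lowest mean in PKC, PKP or PKT HOM was picked from these data. Its depth is thus partly set by the choice. On the 60k arrays, a probe in an intron of Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf (chromosome 4, 88923293 to 88923352), lay at −3.76 ± 0.48 in PKC (n = 16) and at −0.18 ± 0.24 in PKP (n = 16), and all 16 PKC cultures were at −2.74 or below. The other 3 probes of the gene averaged −0.70, −0.86 and −0.85 in PKC. A probe in an intron of Trp53, the gene of the tumour suppressor p53 (chromosome 11, 69397121 to 69397180), averaged −1.67 ± 2.15 in PKP. There 7 of the 16 cultures lay between −4.41 and −2.97, 1 at −0.88 and the others between 0.11 and 0.47. This probe thus does not show the deletion in 9 cultures labelled PKP, and since the ends of the deleted part are not given, their label was not checked. The split largely followed the slides, all scanned on one day. At −2 or below lay 0 of 7 cultures of one slide, 6 of 8 of another and 1 of 1 of the last. It also followed the mouse names: every PKP mouse named with C or KG lay at 0.11 to 0.47, every other at −0.88 or below. The slide with 6 of 8 held both kinds of name, with PKP replicate 14, a KG mouse, at 0.31. Otherwise names and slides ran together, so a batch cause was not separated from a difference in genotype. The second Trp53 probe lay at 0.01 ± 0.16 in PKP. A probe in an intron of Tgfbr2, a receptor for TGF-beta (chromosome 9, 116039878 to 116039937), lay at −3.09 ± 0.19 in PKT HOM (n = 5), at −0.82 ± 0.51 in PKT HET (n = 7) and at −0.12 ± 0.12 in PKC. The highest PKT HOM culture was at −2.91 and the lowest PKT HET culture at −1.69. The other Tgfbr2 probes averaged from −0.24 to −0.02 in PKT HOM. PKT HET replicate 3 was at 0.03, within the PKC range (−0.33 to 0.05), so this probe goes against its label, while the other 6 lay from −1.69 to −0.60.

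As the mean of all probes inside the gene, Cdkn2a lay lower in PKC than in the other 60k cultures by a difference of −0.84 (permutation test, p = 0.0062) and Trp53 lower in PKP by −0.78 (p = 0.00057). The mean of the 12 Tgfbr2 probes differed by −0.17 between PKT and the PKC and PKP cultures (p = 0.0055) and by −0.18 between PKT HOM and PKT HET (exact permutation test, p = 0.321). By the segment mean the latter difference was −0.79 (exact permutation test, p = 0.0139). Without PKT HET replicate 7 the probe mean difference was −0.31 (exact permutation test, p = 0.0022). After normexp background correction the Cdkn2a and Trp53 differences were −0.19 (p = 0.241) and −0.19 (p = 0.159). Under the channel fields, the Cdkn2a probe mean was lower in the culture in 16 of 16 PKC cultures, and all 49 of the larger arrays (metastases among them) and 7 of the 60k arrays with a Cdkn2a segment beyond 2 log2 units had it as a loss. The Trp53 probe mean was lower in 8 of 16 PKP cultures. Chromosome Y beyond 1 was lower on 6 of 7 larger and 2 of 4 of the 60k arrays, which does not fix the direction if some tails came from the other sex. Pooled, 88 of 99 readings (88.9%) were lower, against 34.3% under the labelling text, which contradicts the fields for the larger arrays. Some arrays enter that pool more than 1 time, so no interval is given.

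**Figure D1:**
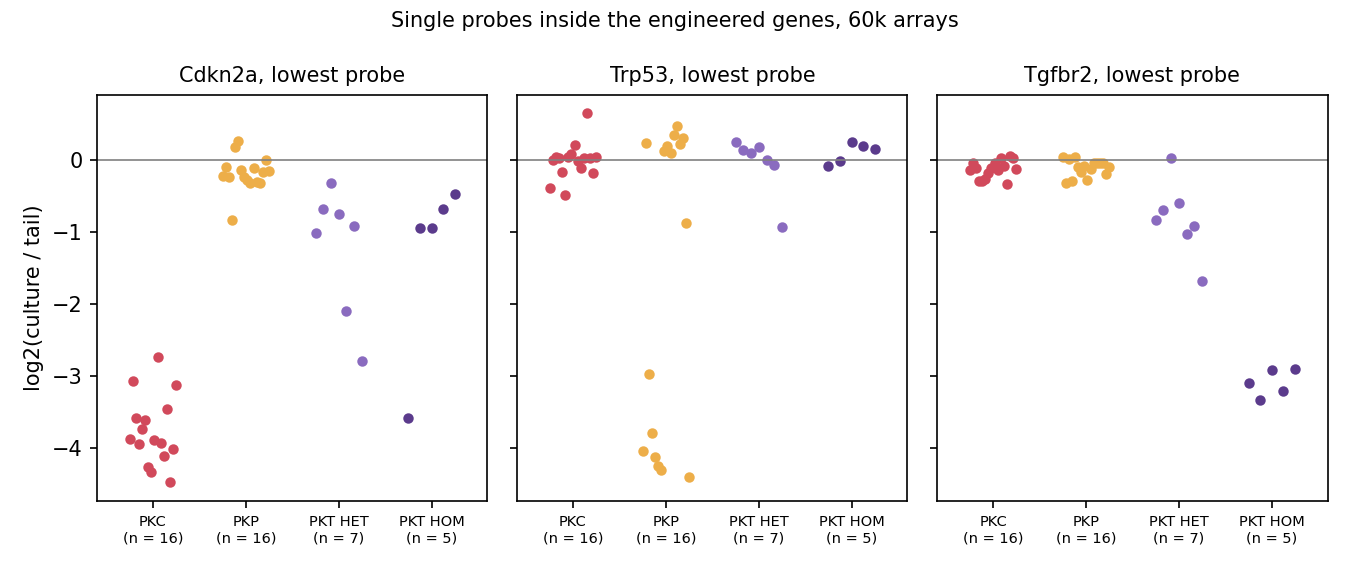
Log2 ratio of culture over tail (vertical axis) at the lowest probe of Cdkn2a, Trp53 and Tgfbr2 in each 60k culture (points) by group (horizontal axis). All 16 PKC cultures lay at −2.74 or below at Cdkn2a, 7 of 16 PKP cultures at −2.97 or below at Trp53, and all 5 PKT HOM cultures at −2.91 or below at Tgfbr2.

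Kras, the oncogene engineered in every mouse (chromosome 6, probes from 145169200 to 145195354), was gained in 11 of 16 PKP cultures (68.8%, interval 41.3% to 89.0%), 8 of 16 PKC (50%, 24.7% to 75.3%), 10 of 17 PKPB (58.8%, 32.9% to 81.6%) and 14 of 38 PK (36.8%, 21.8% to 54.0%). None of the 12 PKT cultures had a Kras gain, which allows a share of up to 26.5%. The Kras segment averaged 0.65 ± 1.03 in PKC, 0.47 ± 0.78 in PKP, 0.22 ± 0.36 in PK, 0.22 ± 0.31 in PKPB and 0.06 ± 0.06 in PKT, and reached 3.58 in a PKC culture. High-level amplification of Kras was found in 4 PKC, 2 PKP and 1 PK cultures. By Fisher's exact test with adjustment over 5 comparisons, the share was lower in PKT than in PKP by a difference of −68.8 percentage points (p = 0.00025, adjusted p = 0.0013) and lower than in PKC by −50 points (p = 0.0084, adjusted p = 0.0209). The latter was −33.3 points (Fisher's exact test, p = 0.114) both at a threshold of 0.15, where 2 PKT HOM cultures counted as gains, and after normexp background correction. The shares did not pass the test between PKP and PKC (difference 18.8 points, p = 0.473), between PKPB and PK (22 points, p = 0.152) or between PKT HOM and PKT HET, with 0 gains in either (p = 1, exact). On the scan day that PKP and PKC share, 11 of 16 and 3 of 6 cultures had the gain (p = 0.624, Fisher's exact test). PKT was scanned on a day of its own, so that for PKT against PKP and for PKT against PKC scan day and genotype cannot be told apart.

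The labels name no Cdkn2a deletion for PK and PKPB, and do not describe PB. Among the listed genes Cdkn2a, with its neighbour Cdkn2b, was the one most often lost there. Deep deletion was found in 24 of 38 PK (63.2%, interval 46.0% to 78.2%) and 10 of 17 PKPB cultures (58.8%, 32.9% to 81.6%), a difference of −4.33 points (Fisher's exact test, p = 0.773), and any loss in 33 and 15 cultures. The Cdkn2a segment had a median of −5.60 in PK and −4.55 in PKPB. In PKT, 12 of 12 cultures had lost Cdkn2a, 3 of them (25%, 5.49% to 57.2%) by a deep deletion, while in PKP 5 cultures had a loss and 0 of 16 a deep deletion (up to 20.6%). Cdkn2b, the neighbouring inhibitor p15, was deeply deleted in 23 PK, 10 PKPB, 3 PKC, 2 PKT and 0 PKP cultures, and Mtap, a gene of methionine salvage nearby, in 9 PK, 7 PKPB, 1 PKC, 2 PKT and 0 PKP cultures. Farther out, deep deletions took in Ifne in 8 PK and 5 PKPB cultures, Ifna1 in 6 and 4, Dmrta1 in 3 and 6, Klhl9 in 3 and 2 and Ifna2 in 3 and 2, and in PKPB also Elavl2 in 3, Ifnb1 in 3, Mllt3 in 2 and Focad in 2 cultures. After normexp background correction the PK share of Cdkn2a deep deletions was 31.6%, and the difference to PK was 27.2 points in PKPB (p = 0.0769).

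**Figure D2:**
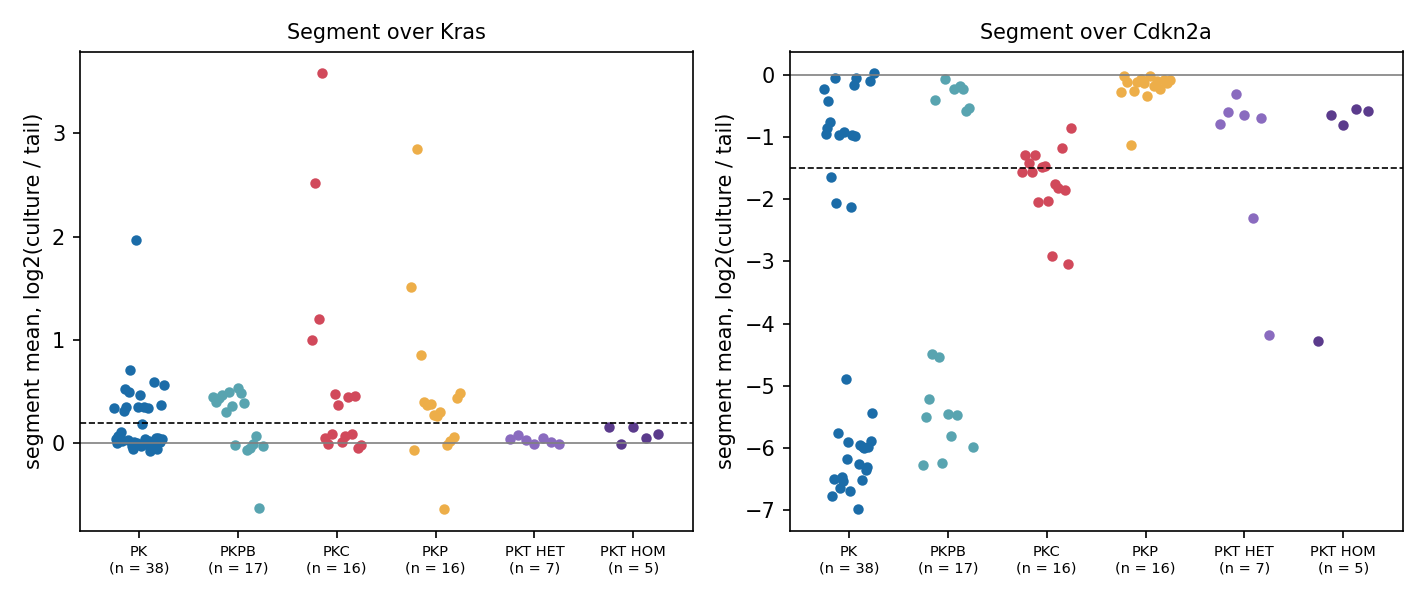
Segment mean (log2 of culture over tail, vertical axes) over Kras and over Cdkn2a in each primary culture (points) by group (horizontal axis). The dashed lines mark the gain threshold of 0.2 and the deep deletion threshold of −1.5, and no PKT culture exceeded 0.16 at Kras.

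Whether Kras gain and loss of other genes went together was tested within PK, PKPB and both (15 relations in the family). In PKPB, 8 of 10 cultures with a Cdkn2a deep deletion and 2 of 7 without it had a Kras gain (Fisher's exact test, p = 0.0584, adjusted p = 0.876). In PK the counts were 9 of 24 and 5 of 14 (Fisher's exact test, p = 1). Across the 17 PKPB cultures the Kras and Cdkn2a segment values had Pearson's r of −0.52 (permutation p = 0.0282, adjusted p = 0.423) and Spearman's rho of −0.36 (permutation p = 0.152, adjusted p = 0.404), and r without the 2 cultures farthest from the median was −0.45. In PK, r was −0.01 (permutation p = 0.953) and rho 0.13 (p = 0.442), with r of −0.03 without 2 cultures, and within the 2 scan days that hold most PK cultures r was −0.09 (n = 16, permutation p = 0.733, rho −0.24) and −0.11 (n = 19, permutation p = 0.824, rho 0.13). In both genotypes together r was −0.15 (permutation p = 0.308) and rho −0.01 (p = 0.960), and r without 2 cultures −0.16. PKPB scan days held too few cultures to repeat this within a day. For Kras gain with gains of Myc, Yap1 or Nfkb2 or with Trp53 loss, the lowest Fisher p was 0.157 (Nfkb2 in both genotypes, 6 of 9 against 18 of 46), and no relation passed adjustment.

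Among the other named genes, Myc, a growth-promoting transcription factor on chromosome 15, was gained in 6 PKP, 4 PK, 2 PKT, 1 PKPB and 0 PKC cultures, with high-level amplification in 4 PKP and 2 PK cultures. Nfkb2, a subunit of NF-kappaB on chromosome 19, was gained in 7 PK, 6 PKP, 5 PKT, 2 PKPB and 1 PKC cultures and lost in 3 PKT cultures. Smad4, the shared mediator of TGF-beta signalling, was lost in 5 PKT, 4 PKP, 1 PK, 0 PKC and 0 PKPB cultures, and Tgfbr2 in 5 PKT, 4 PK, 3 PKP, 0 PKC and 0 PKPB cultures. Trp53 was lost in 7 PKP, 2 PK, 2 PKT, 1 PKC and 0 PKPB cultures. Tgfbr2 in PKT and Trp53 in PKP were deleted by design, and a call needs a segment of at least 3 probes. The single Tgfbr2 probe given above lay at −2.91 or below in all 5 PKT HOM cultures, while their Tgfbr2 segments reached up to −0.08. The PKT count of Tgfbr2 and the PKP count of Trp53 are thus not counts of cultures with the engineered deletion. Gata6, a transcription factor of pancreatic development, was lost in 3 PKP, 2 PK, 1 PKT, 0 PKC and 0 PKPB cultures and gained in 1 PKPB culture. Yap1, a transcriptional coactivator, was gained in 3 PK, 1 PKPB, 1 PKT, 0 PKC and 0 PKP cultures. These counts were not tested between genotypes.

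On the 60k arrays the share of the autosomal genome gained or lost was 6.33% ± 4.60 in PKC (n = 16), 18.3% ± 16.1 in PKP (n = 16) and 20.1% ± 13.9 in PKT (n = 12), of which 16.3% ± 16.6 in PKT HET and 25.4% ± 7.63 in PKT HOM. On the larger arrays it was 13.7% ± 13.7 in PK (n = 38) and 15.2% ± 13 in PKPB (n = 17). In PKT losses took 13.4% ± 6.36 and gains 6.72% ± 9.05. By permutation tests adjusted over 5 comparisons, PKT exceeded PKC by 13.7 points (p = 0.00022, adjusted p = 0.0011) and PKP exceeded PKC by 12.0 points (p = 0.0048, adjusted p = 0.0119). PKT and PKP differed by 1.78 points (p = 0.762), by 5.76 at a call threshold of 0.3 (p = 0.0499), by −1.70 with the GC correction (p = 0.719) and by 5.31 with slides as units (exact permutation test, p = 0.5). PKPB and PK differed by 1.49 (p = 0.71), and PKT HOM and PKT HET by 9.16 (exact permutation test, p = 0.294). On the shared scan day, PKP exceeded the 6 PKC cultures (7.21% ± 5.81) by 11.1 points (exact permutation test, p = 0.115), and with whole slides as units the difference was 8.78 points (exact, p = 0.114, 35 splits). PKT against PKC gave 14.1 points with slides as units (exact, p = 0.0286, the smallest that 35 splits can give). PKT shared no scan day with PKC or PKP, so in its comparisons with them scan day and genotype cannot be told apart. PKPB against PK gave 0.432 points with scan days as units (exact permutation test, p = 0.943). With slide as a block, PKT HOM exceeded PKT HET by 6.53 points (exact permutation test, p = 0.417), and within the 3 slides by 11, −3.50 and 16.6 points. Without PKT HET replicate 7, which lay at 52.4%, that difference was 15.2 points (exact permutation test, p = 0.0087).

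**Figure D3:**
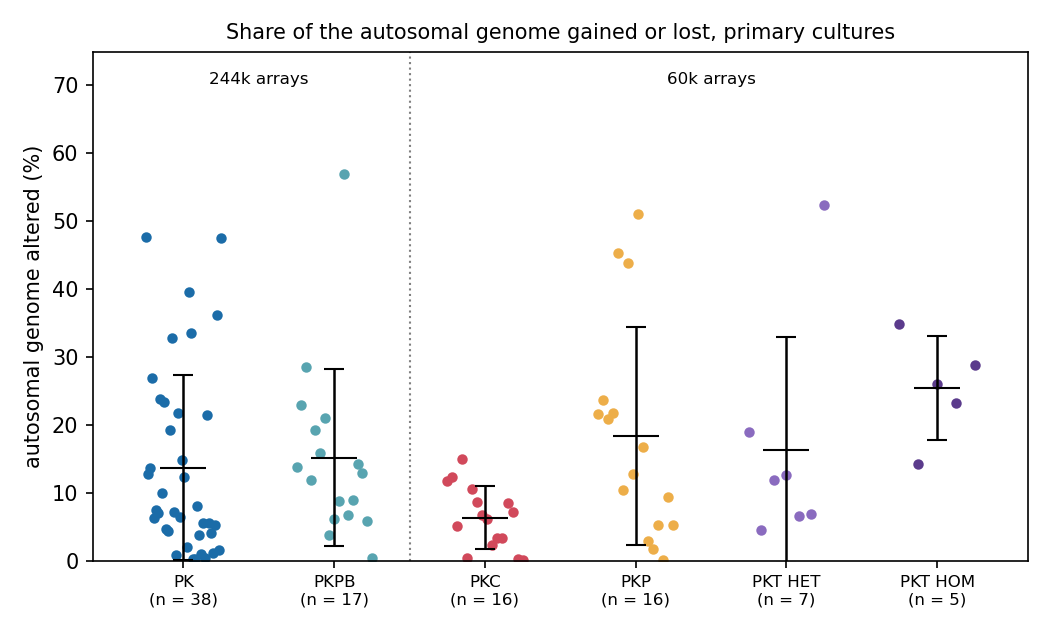
Percent of the autosomal genome gained or lost (vertical axis) in each primary culture (points) by group (horizontal axis), with mean and SD (bars, which end at 0). PKC cultures stayed at or below 15%, while PKP reached 51.1% and 1 PKT HET culture 52.4%.

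Loss of chromosome 4, which holds Cdkn2a, and gain of chromosome 6, which holds Kras, recurred as whole-chromosome events in more than 1 genotype, and gain of chromosome 19 in PKT. Chromosome 4 was lost in 7 of 12 PKT (58.3%, interval 27.7% to 84.8%, adjusted p = 0.0038) and 8 of 38 PK cultures (21.1%, 9.55% to 37.3%, adjusted p = 0.0038), both past the permutation test. Its loss in 3 of 17 PKPB (adjusted p = 0.0522) and 2 of 16 PKC cultures (adjusted p = 0.117) did not pass it. Chromosome 6 was gained in 6 of 16 PKP (37.5%, adjusted p = 0.0038), 6 of 17 PKPB (35.3%, adjusted p = 0.0038), 4 of 16 PKC (25%, adjusted p = 0.0063) and 8 of 38 PK cultures (21.1%, adjusted p = 0.0038, permutation tests). Chromosome 19 was gained in 3 of 12 PKT cultures (25%, adjusted p = 0.0353, permutation test), and its gain in 4 of 16 PKP cultures (adjusted p = 0.0969) and the loss of chromosome 12 in 4 of 12 PKT cultures (adjusted p = 0.0929) did not pass. Between genotypes no whole-chromosome share passed adjustment (lowest adjusted p = 0.564, Fisher's exact test, for chromosome 4 loss in PKT against PKC, 7 of 12 against 2 of 16).

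**Figure D4:**
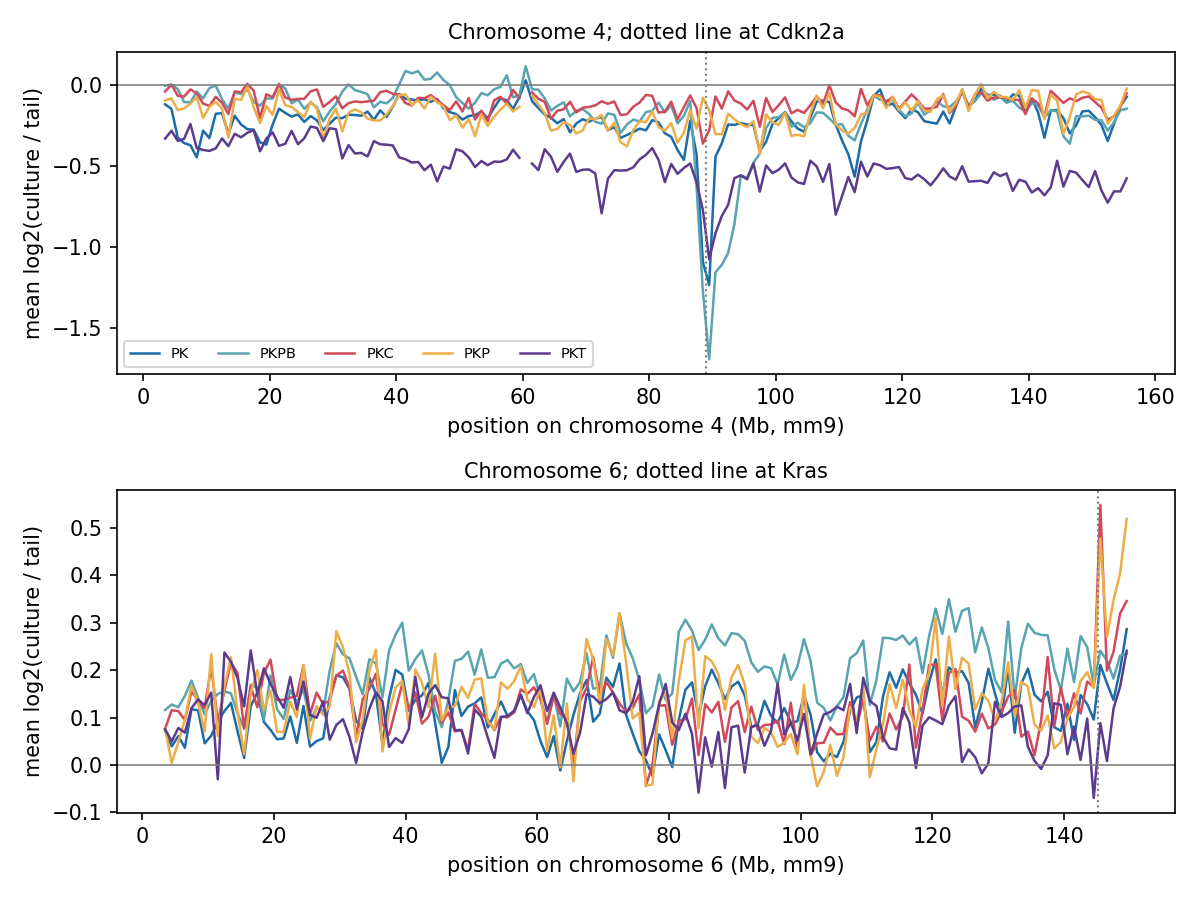
Mean log2 ratio per 1 Mb bin (vertical axes) along chromosomes 4 and 6 (horizontal axes, Mb, mm9) for the primary cultures of each genotype (lines). On chromosome 4 the PKT mean lay between −1.07 and −0.24, and the lowest bin of PKPB, at −1.69, starts at 89000001. On chromosome 6 the PKC mean peaked at 0.55 in the bin of Kras, which starts at 145000001.

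Focal events recurred at Cdkn2a, Kras and Myc. Deep deletions around Cdkn2a (chromosome 4) peaked in PK at 89000001 to 90000000, the bin next to that of Cdkn2a, which holds Dmrta1 and Zfp352 and was reached by a deep segment in 26 of 38 cultures (Cdkn2a itself in 24, Dmrta1 in 3). They peaked at 88000001 to 90000000 in PKPB (10 of 17) and at 88000001 to 89000000 in PKT (3 of 12) and in PKC (9 of 16), where Cdkn2a was deleted by design. High-level amplification recurred at 144000001 to 147000000 on chromosome 6 in PKC (4 of 16 cultures, over Kras) and at 61000001 to 63000000 on chromosome 15 in PKP (4 of 16, over Myc). In all, 22 regions passed the familywise permutation test, with p of 0.001, the smallest that 1000 shifts can give, to 0.009. In PK the other 9 were on chromosome 4 as well. They were led by 111000001 to 114000000 (7 cultures), 9000001 to 11000000 (6 cultures, over 2610301B20Rik, Ndufaf6 and Plekhf2), 25000001 to 26000000 (5 cultures, over Fhl5, Fut9 and Ufl1) and 83000001 to 84000000 (5 cultures). PKPB had 1 at 6000001 to 7000000 (3 cultures). PKT had deep deletions at 97000001 to 98000000 on chromosome 4 (6 cultures, over Nfia and E130114P18Rik) and at 123000001 to 125000000 (5 cultures). On chromosome 6, deep deletions recurred at 129000001 to 130000000 in PKC (4 cultures) and PKP (3 cultures). In PKP, amplification was also called at 90000001 to 91000000 on chromosome 3 (7 cultures) and at 13000001 to 14000000 on chromosome 2 (4 cultures). Each lay over segments of 3 probes that include a raised exonic probe, of S100a6 and of Vim. Many of these segments had only 3 probes. At the other thresholds for amplification and deep deletion 14 of the 22 regions were called, among them neither of these 2 PKT regions away from Cdkn2a, 5 of 10 in PK and 1 of 2 in PKPB. When segments needed 5 probes, 7 of the 22 regions were still called, those at Cdkn2a, Kras and Myc and that at 111000001 to 114000000 in PK.

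PKPB and PK, which differ in PB, differed in few 1 Mb bins: limma called 14 bins higher and 20 lower of 2403. These counts depended on the scaling: 31 and 7 when centred on the highest peak of segment means, 8 and 2 with the authors' own centring and 9 and 96 after normexp. Among the called bins the largest differences were on chromosome 12, where PKPB lay at 0.04 ± 0.11 (n = 17) and PK at −0.15 ± 0.13 (n = 38) at 18000001 to 21000000 (difference at the peak 0.22, SE 0.04, limma adjusted p = 0.0055). Higher regions were also at 23000001 to 25000000 (0.17) and 108000001 to 109000000 (0.17, over 3110018I06Rik) on the same chromosome, at 3000001 to 4000000 on chromosome 14 (0.21) and at 133000001 to 134000000 on chromosome 5 (0.16, over Auts2). Lower regions by size were at 77000001 to 78000000 (−0.15, over Usp25 and Gm11146), 55000001 to 56000000 (−0.13) and 58000001 to 59000000 (−0.12) on chromosome 16 and at 131000001 to 133000000 (−0.13) and 144000001 to 145000000 (−0.12) on chromosome 3. None of these regions held a gene of the lists. Larger differences beside Cdkn2a, such as −1.15 in PKPB and −0.44 in PK at 90000001 to 91000000 on chromosome 4, were not called. The groups shared no scan day. With scan day as a random block limma called 39 bins, at a fitted block correlation of −0.0036, which cannot tell genotype from scan day. With bins of 5 Mb or with segment means limma called 0, with 63 and 256 bins at an unadjusted p under 0.05.

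PKP differed from PKC in many bins by small amounts: limma called 74 bins higher and 220 lower in PKP of 2391 (283 and 124 after normexp, which turns the balance), the higher ones mostly on chromosomes 2 (27 bins) and 5 (19) and the lower ones on chromosomes 7 (45), 10 (42) and 18 (38). Named by the difference at the peak bin, called regions included a lower stretch at 47000001 to 48000000 on chromosome 7 (−0.34 ± 0.20 in PKP and −0.10 ± 0.07 in PKC, n = 16 each, limma adjusted p = 0.0018) and a higher one at 26000001 to 27000000 on chromosome 14 (0.15 ± 0.24 and −0.07 ± 0.09, limma adjusted p = 0.0345). Other lower regions were at 10000001 to 12000000 on chromosome 7 (−0.25), 54000001 to 55000000 on chromosome 18 (−0.20, over Csnk1g3), 25000001 to 27000000 on chromosome 1 (−0.22, over Adgrb3) and 76000001 to 77000000 on chromosome 4 (−0.20, over Ptprd). Other higher regions were on chromosome 2, at 152000001 to 153000000 (0.21), 154000001 to 156000000 (0.21) and 158000001 to 159000000 (0.20), and at 134000001 to 136000000 on chromosome 5 (0.20). The bins of Kras, Cdkn2a and Trp53 were not among the regions named here, which are limited to bins that limma called. The Cdkn2a bin, at −0.36 in PKC and −0.08 in PKP, was not called. With scan day as a block limma called 5 bins, and within the shared scan day (16 PKP, 6 PKC) 0, with 316 at an unadjusted p under 0.05. On segment means it called 0, with 643 at an unadjusted p under 0.05, and centring on the highest peak of segment means gave 23 higher and 18 lower.

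PKT stood apart through lower copy number of chromosome 4. Against PKC, limma called 17 bins higher and 260 lower, of which 139 were on chromosome 4, 91 on chromosome 12 and 24 on chromosome 14. The longest region, at 73000001 to 156000000 on chromosome 4, holds Cdkn2a, Cdkn2b, Mtap, Arid1a, a chromatin remodeller, Jak1, a cytokine receptor kinase, and Mycl, and at its peak, over Elavl2, the difference was −0.84 (SE 0.20, limma adjusted p = 0.0023). Averaged over the region, PKT lay at −0.58 ± 0.23 (n = 12) and PKC at −0.12 ± 0.12 (n = 16). The mean of all chromosome 4 bins was below 0 in 12 of 12 PKT cultures, from −0.81 to −0.12. Chromosome 4 was also lower at 31000001 to 60000000 (−0.50, over Tgfbr1), 61000001 to 72000000 (−0.44) and 21000001 to 23000000 (−0.38), and chromosome 12 at 19000001 to 20000000 (−0.36, over Gm21863). PKT was higher on chromosome 19 at 49000001 to 51000000 (0.27), 19000001 to 20000000 (0.22, over Rorb) and 27000001 to 28000000 (0.22), on chromosome 9 at 124000001 to 125000000 (0.18, over Ccr2 and Ccr5, but −0.0183 in bins of 5 Mb) and on chromosome 10 at 96000001 to 97000000 (0.18, over Btg1 and Dcn). With slide as a random block limma called 309 bins, but the fitted block correlation was −0.02, so this block did not widen the errors. No slide and no scan day held both groups, so this fit cannot tell genotype from batch.

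Against PKP, limma called 368 bins higher and 531 lower in PKT, with most of the lower bins on chromosomes 4, 12 (77 bins) and 2 (74 bins). The region from 85000001 to 156000000 on chromosome 4 lay at −0.60 ± 0.23 in PKT (n = 12) and −0.16 ± 0.14 in PKP (n = 16), with a peak difference of −0.92 (SE 0.20, limma adjusted p = 0.00041) over Dmrta1 and Zfp352. Other lower regions were at 25000001 to 28000000 on chromosome 14 (−0.47), a stretch that holds a raised exonic probe of Arf4, at 39000001 to 50000000 on chromosome 4 (−0.49), 125000001 to 126000000 on chromosome 14 (−0.35, over Fgf14) and 21000001 to 22000000 on chromosome 12 (−0.36). Higher regions were at 124000001 to 125000000 on chromosome 9 (0.24, over Ccr2 and Ccr5), 71000001 to 72000000 on chromosome 13 (0.23), 63000001 to 66000000 on chromosome 10 (0.26, over Ctnna3), 54000001 to 56000000 on chromosome 18 (0.27, over Csnk1g3) and 49000001 to 51000000 on chromosome 19 (0.24, but −0.10 in bins of 5 Mb). PKT was scanned on a day without PKP, so genotype and scan day cannot be told apart, and the 2 PKT comparisons share the PKT cultures. Centring on the highest peak of segment means gave 142 higher and 660 lower bins.

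Between PKT HOM and PKT HET limma called 0 bins, with 177 at an unadjusted p under 0.05 and 4 with slide as a block. Without PKT HET replicate 1 it called 3 bins, all lower in PKT HOM.

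Profiles of metastases correlated more with the primary of the same mouse than with other primaries. In 7 PK mice with 16 metastasis cultures, the correlation across 1 Mb bins was 0.62 ± 0.23 (SD over mice) with the primary of the same mouse. With the other primaries it was 0.20 ± 0.08, a difference of 0.42 ± 0.29 (one-sided exact permutation test of mouse labels, p = 0.000198). This p is the smallest that all permutations of the mice can give. The own primary was the closest in 6 of 7 mice. Per the labels, both ratios of a mouse are taken over tail DNA of that mouse, which the permutation does not remove. The lymph node metastasis had chromosome X at −0.90 and Y at 3.03, so its tail may be of another mouse. In bins without a gain or loss in either culture the correlations were 0.54 ± 0.13 and 0.45 ± 0.15. Their difference was 0.09 ± 0.17 (one-sided exact permutation test, p = 0.0232), so part of the 0.42 need not come from copy number of the tumours. In 1 mouse the metastasis was scanned on the day of its primary, where the own correlation was 0.74, and in the others on another day. The altered share was 14.3% ± 13.4 in metastases and 13.9% ± 12.1 in primaries, a difference of 0.395 points ± 13, higher in 3 of 7 mice (exact sign-flip permutation test, p = 0.969). Limma called 0 bins between metastasis and primary, with 167 at an unadjusted p under 0.05. The difference in altered share was −3.18 points without mouse 6, whose only metastasis culture was the highest above its primary, and −1.58 without mouse 4.

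Gene lists were scored by the share of cultures with a gain minus that with a loss, averaged over the 1 Mb bins that hold the members, against shifted positions (permutation tests, adjusted over 8 lists in 5 genotypes). On simulated data this test missed many planted losses and called some unchanged lists, so its calls and misses are weak evidence. Genes of KRAS and receptor signalling were gained on balance in PK (10.5%, against −1.94% ± 3.22 in shifted genomes, adjusted p = 0.0080), PKPB (14.7%, adjusted p = 0.0307) and PKP (16.1%, adjusted p = 0.0465), led by Kras in each. Kras, Met, Braf and Raf1 of this list all lie on chromosome 6, whose gain recurred in these genotypes. The calls thus need not speak for the other members. The same list did not pass in PKC (7.59%, adjusted p = 0.121) or PKT (−3.57%, adjusted p = 0.909). In PKT, Met, a receptor kinase on chromosome 6, was gained and Nf1 lost in 4 of 12 cultures each. Cell cycle and p53 suppressors were lost on balance in PK (−11.8%, adjusted p = 0.0331) and PKC (−11.5%, adjusted p = 0.0130), led by Cdkn2a. Cdkn2b, another member, shares the Cdkn2a bin, and in PK each of the 2 genes was lost in 33 of 38 cultures. The PK call thus need not speak for the other members. In PKC the Cdkn2a loss is the engineered deletion, so the PKC call does not speak for loss beyond the design. Cdkn1b on chromosome 6 was the member most often gained in PK (13 of 38), PKPB (10 of 17) and PKP (9 of 16). That list did not pass in PKPB (−4.41%, adjusted p = 0.765), PKP (1.04%, adjusted p = 0.909) or PKT (−20.8%, adjusted p = 0.194), where Pten had 5 gains. The chromosome 4 neighbours of Cdkn2a were lost on balance in PK (−73.4%, adjusted p = 0.0080), PKPB (−67.1%, adjusted p = 0.0152) and PKC (−58.1%, adjusted p = 0.0080), and at −94.2% in PKT (adjusted p = 0.0582) and −38.1% in PKP (adjusted p = 0.241) did not pass. Most of these neighbours share a bin with Cdkn2a, so the bins also hold the Cdkn2a deletion, which in PKC was engineered. Scored by the segments over the members' own probes, the neighbours were at −52.4% in PK (adjusted p = 0.0107), −50.6% in PKPB (adjusted p = 0.120) and −21.9% in PKC (adjusted p = 0.204, permutation tests), so that only PK passed. Mtap was the neighbour most often lost in PK (24 of 38 cultures), Dmrta1 and Elavl2 in PKC (5 of 16 each). By the same score KRAS and receptor signalling did not pass in PKP (14.7%, adjusted p = 0.0844). With the mean taken per chromosome first, only 3 of the 8 calls were left, those of the neighbours in PK, PKPB and PKC, and none of KRAS signalling or the suppressors. After normexp 5 were left, without KRAS signalling in PKP and the suppressors in PK and PKC.

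The other lists passed in no genotype. The TGF-beta pathway was at −2.89% in PK, −0.588% in PKPB, −1.25% in PKC, −8.13% in PKP and −16.7% in PKT (adjusted p from 0.558 to 1). Its members included Tgfbr1 on chromosome 4 lost in 9 of 12 PKT and 9 of 38 PK cultures and Acvr1b gained in 4 PKP cultures. Amplified oncogenes were at 1.13%, 2.10%, −0.446%, 0 and −8.93% in that order (adjusted p from 0.725 to 0.986). Calls led with Mycl lost in 11 PKT and 12 PK cultures, Ccne1 lost in 8 PKP, Cdk4 gained in 5 PKPB and Myc and Nfkb2 gained in 6 PKP cultures each. Chromatin remodelling genes were at 2.63%, 1.76%, −3.13%, 6.88% and −15% (adjusted p from 0.558 to 0.909), with Arid1a lost in 12 of 12 PKT cultures and Smarca2 gained in 5 of them. Immune recognition genes were at 2.37%, 0.588%, −2.5%, 3.13% and −11.7% (adjusted p from 0.725 to 0.955), with Jak1 lost in 10 PKT and 9 PKP and Jak2 gained in 4 PKT and 4 PKP cultures. The copy number control genes were at 3.8%, 7.19%, 3.47%, 15.3% and −7.41% (adjusted p from 0.178 to 1), with Gapdh, on chromosome 6, gained in 13 PK, 10 PKPB, 9 PKP and 4 PKC cultures.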

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

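The tests chosen only after the result was seen were those of neighbouring probes and GC content at raised probes, of shared ends and of chromosome share for the deletions of chromosome 4, of the side of chromosome X probes, and the counts over other splits of the samples.

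Among 13 groups of 5 to 7 values, 3 held a value far from the others, where chance gives about 1 in 20 groups. PKT HET replicate 7 had 52.4% of its autosomal genome altered, against 4.56% to 19% in the other 6 PKT HET cultures, and the mean of its Tgfbr2 probes was −0.96, against −0.14 to 0.08. PKT HOM replicate 1 had a Cdkn2a segment at −4.28, against −0.80 to −0.55 in the other 4 PKT HOM cultures. No biological explanation was tested for these 3 values.

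On 3 arrays chromosomes X and Y, which entered no comparison, lay off 0 in opposite directions: the PK lymph node metastasis (X −0.90, Y 3.03), PKP replicate 13 (X −0.83, Y 2.47) and PKP replicate 5 (X 0.44, Y −1.59). The Y mean was at −1 or below on 7 other arrays (3 PK, 3 PKPB and 1 PKP) and at 1 or above on 1 other, PKP replicate 8 (1.41). Exchanged channels would turn the sign of deletions. They are argued against for the lymph node metastasis (Cdkn2a segment −6.35) and PKP replicate 5 (Trp53 probe −4.13), but stay open for PKP replicate 13 (Trp53 probe 0.23). The lowest correlation of the 3 arrays with the mean of their genotype was 0.354. It does not decide, since PK metastases and primaries of other mice correlated at 0.45 even in bins without gain or loss. A tail from a mouse of the other sex may lie behind the 3 arrays, as at least 96.9% of X probes lay on the side of the mean. X at 0.44 in PKP replicate 5 is below the shift of about 1 this would give, so that array stays open. No biological explanation was tested.

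On the 60k arrays 10 probes stood at least 0.5 above their neighbours, among them exonic probes of S100a6 (1.79 ± 0.83 above, SD, n = 44), Vim (1.73 ± 0.87) and Ahnak (1.25 ± 0.76), and 0 of the 10 were raised on the larger arrays of PK and PKPB. GC content is argued against, as 100% of the probes stayed raised after its correction. A DNA gain around them stays open: the median of the neighbours within 100 kb was 0.0993 (−0.05 to 0.21 over the probes), but the probes were picked for standing above their neighbours. RNA of the culture labelled with its DNA is a candidate explanation: of 8 raised exonic probes of one strand, 100% (interval 63.1% to 100%) were in the sense of the transcript, against 50.9% of all exonic probes (one-sided binomial p = 0.0045), though it leaves out the other 2 raised probes, which lie outside exons. Each of the 8 raised exonic probes stood highest in PKP, such as that of Arf4 (1.23 in PKP, 0.45 in PKC and 0.33 in PKT). RNA may also bear on the PKP amplifications called at S100a6 and Vim. It may bear too on bins that hold such probes in the comparisons with PKP, which was not tested. No biological explanation was tested.

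In PK, 16 of 38 cultures had deep deletions in 9 regions of chromosome 4 away from Cdkn2a. A single long deletion from Cdkn2a is argued against, since the median of the probes in between lay above −1.5 in 100% of the 16 cultures (−0.996 to 0.42). Culture and tail from different mice are argued against too, as 90.7% of the deep segments of these cultures outside Cdkn2a were on chromosome 4. The cultures were picked for deep segments on that chromosome, which raises this share in part. Deletions inherited on one parental chromosome and uncovered by loss of the other may explain them but stay open: 46.9% of the ends lay at the same probe in another mouse, below the 50% set for this, while equally many drawn Cdkn2a stretches shared 22.4% on average (p = 0.0001, the smallest that 10000 draws can give) and all Cdkn2a stretches 64.6%. The comparison with drawn stretches was adopted after that with all of them was seen.

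Other splits of the same samples were compared with the real ones by the number of bins limma called. For PKP against PKC (294 bins, highest other split 9), PKT against PKC (277, highest other 101) and PKT against PKP (899, highest other 77), 1 of 100 splits, the real one, gave as many. Random groupings of single arrays thus did not reach these counts. The splits shuffled arrays across scan days, so they cannot tell genotype from scan day. For PKP against PKC limma called 5 bins with scan day as a block and 0 within the shared scan day. For PKPB against PK 2 of 100 splits, the real one included, gave as many as the real 34, and the other of these gave 68. This share is under 0.05, but it rests on few splits. These also shuffled arrays across scan days, of which the 2 genotypes shared none. Neither chance nor scan day is thus excluded. With bins of 5 Mb or segment means limma called 0 bins there (63 and 256 at an unadjusted p under 0.05). For PKT HOM against PKT HET the real count was 0, which all 100 splits reach whatever the data, so this comparison says nothing on chance. Another split gave 545 bins, and what lies behind that count was not examined. For metastasis against primary the real count was also 0, which all 64 splits reach, and the highest other gave 104, so it says nothing on chance either.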

How the results depend on the processing

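The GC correction, the authors' own centring, the shared probes, the shared scan day, whole slides, segments of at least 5 probes, the members' own calls, the bins without gain or loss and leaving out PKT HET replicates were tests chosen after the result was seen. For 37 main results 408 values were recomputed: 368 kept direction and side of the threshold, and 17 results kept them under every alternative tried on them. Of 8486 values of single genes, lists and regions, 8114 did so, 202 moved, 36 reversed, 12 became stronger and 122 weaker. The median-centred authors' tables, leaving out probes dim in the tail and leaving out the 3 arrays with discordant X and Y changed none of the 37, 33 and 17 main results each was tried on. For the changes below the cause was not tested.

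With normexp, PKPB against PK gave 105 bins (9 higher, 96 lower), focal regions numbered 14 and lists past the threshold 5. The engineered Cdkn2a and Trp53 differences were −0.19 each, Kras gain in PKT against PKC −33.3 points (Fisher's exact p = 0.114), Cdkn2a deep deletion 31.6% in PK and its difference in PKPB 27.2 points. Kras with Yap1 gave 11.1 points in PK and −10 in PKPB, and list scores less the shifted mean were 0.933 (TGF-beta) and 0.0152 (suppressors) in PKPB and 1.43 (oncogenes) and 6.92 (immune) in PKT. With the authors' own centring, PKPB against PK gave 10 bins (8 higher, 2 lower), PKP against PKC 51 (22 and 29) and PKT against PKP 827 (166 and 661). List scores were −0.355 (chromatin) and −0.351 (immune) in PKPB, −1.16 (control) in PKC, and 0.00639 (control) and 1.92 (immune) in PKT. Centred on the highest peak, PKP against PKC gave 41 bins (23 and 18) and PKPB against PK 38 (31 and 7), Kras with Cdkn2a in PK −5.36 points, and list scores −0.488 (immune, PKPB), −0.971 (control, PKC), 0.642 (oncogenes, PKT) and 1.73 (control, PKT). With normexp, PKP against PKC split into 283 and 124 and PKT against PKC into 48 and 238.

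With the GC correction, PKPB against PK gave 74 bins, the altered share in PKT less PKP −1.70 points, Kras with Yap1 in PK 13.9 points, and list scores −0.113 (chromatin, PK), −0.522 (oncogenes), −3.81 (chromatin) and −2.64 (immune) in PKPB, −0.153 (oncogenes) and −3.53 (suppressors) in PKP, and 3.21 (oncogenes), 6.65 (control) and 5.07 (immune) in PKT. The shared probes gave 77 bins for PKPB against PK and 13.9 points for Kras with Yap1 in PK. Bins of 5 Mb gave 0 for PKPB against PK, 70 for PKP against PKC, 63 for PKT against PKC and 185 for PKT against PKP. There were fewer bins to test. Differences were −0.0183 at the chromosome 9 region of PKT against PKC and −0.10 at the chromosome 19 region of PKT against PKP. Segment means gave 0 limma bins for PKPB against PK and for PKP against PKC (256 and 643 at an unadjusted p under 0.05), and −0.79 for Tgfbr2 in PKT HOM against PKT HET (exact permutation p = 0.0139). For PKP against PKC, the fit of only these groups gave 444 bins, scan day as a block 5 and the shared scan day 0 in limma (316 at an unadjusted p under 0.05). The altered share differed by 8.78 points over whole slides and 11.1 on the shared day.

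Lists averaged per chromosome first passed in 3 cases, all of the chromosome 4 neighbours, with scores of −0.215 (immune, PK), 1.83 (suppressors, PKPB), −4.36 (immune, PKPB), −4.65 (immune, PKP), −0.353 (KRAS, PKT) and 0.766 (control, PKT). By the members' own calls 5 passed, with −2.49 (suppressors, PKP) and 1.71 (control, PKT). A whole-chromosome rule of 50% gave 11 events past the threshold, segments of at least 5 probes 10 focal regions, a Kras threshold of 0.15 −33.3 points for PKT against PKC (Fisher's exact p = 0.114), and the turned sign of the larger arrays 34.3% of anchors. The altered share of PKT less PKP was 5.76 points at a threshold of 0.3 (p = 0.0499), and of PKT HOM less PKT HET 14.3 without the noisiest arrays (exact permutation p = 0.0095).

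Leaving out each PKT HOM replicate, PKT HOM against PKT HET gave 0 bins each time, Tgfbr2 −0.21 to −0.15 and an altered share of 6.80 to 12.0 points. Leaving out each PKT HET replicate gave 0 to 3 bins, −0.31 to −0.14 and 7.21 to 15.2 points, with −0.31 and 15.2 without replicate 7 and 3 bins without replicate 1. Leaving out each mouse, metastases gave 0 bins and −3.18 to 2.84 points of altered share (−1.58 without mouse 4, −3.18 without mouse 6), and own-mouse correlation exceeded the others by 0.35 to 0.49. In bins without gain or loss it exceeded them by 0.09 (one-sided exact permutation p = 0.0232). Without the pairing of metastasis and primary by mouse (no replicate block), limma called 0 bins as well (111 at an unadjusted p under 0.05). Signal over background limited few spots, as at least 98.1% were well above it.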

Other observations

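The values here were noticed after the data were seen and were not tested between genotypes. Smarca2, a chromatin remodeller on chromosome 19, was lost in 5 of 16 PKC cultures (segment mean −0.30 ± 0.51, SD) and gained in 5 of 12 PKT cultures (0.18 ± 0.24), while PK had 4 gains and 0 losses of 38 and PKP 3 of each of 16. Arid1a on chromosome 4 was at −0.62 ± 0.24 in PKT (n = 12) and −0.12 ± 0.53 in PK (n = 38), where 10 cultures had a loss and 5 a gain.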
